A study of Danio rerio with 9 samples.

How the data were processed

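RNA was measured by sequencing in 9 samples of zebrafish (Danio rerio) intestine. Per the labels' protocols, total RNA was harvested with a Qiagen RNeasy kit, 1.3 µg of it went into each library, and libraries were made with a SMARTer mRNA kit. The design text gives 3 groups, FM, SBM and D3, with 3 replicates each, and the group of each library was taken from its title. The labels do not spell out the 3 codes, and give no dose, time, sex or diet. They do not say whether the replicates were separate fish or pools, so p-values measure only the spread between these samples, which may be technical in part. Whether the kit or the counting kept the strand is also unstated, so reads of overlapping and antisense genes cannot be told apart.

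The deposited count table holds raw whole-number counts per gene for the 9 libraries, and the sequencing reads themselves were not used here. The aligner, the counter, the genome build and the annotation are not given in the sources used here, and no coordinates are printed. The authors also deposited an FPKM table (fragments scaled by gene length and library size). From the values, each deposited FPKM is the count divided by 1 length per gene and by the library's total: the largest relative deviation was 0.00012%, and the implied length was a whole number within 0.01 for 26982 of 26983 genes. The FPKM table therefore holds the same measurement and was used only for alternatives. No gene has a count of 0 in every library. Of the 26983 names, 21330 matched a current RefSeq symbol (assembly GRCz12tu, used for names only), 1426 matched a synonym only, 5572 are LOC names, and 10 have the form of a date.

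Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 19450 genes and removed 7533. Library sizes were scaled by TMM factors, which ran from 0.846 to 1.204. All 9 libraries entered 1 quasi-likelihood fit with a mean per group and 6 residual degrees of freedom. The common dispersion was 0.255, a biological coefficient of variation of 50.5%. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the test's F. CPM (counts scaled by library size) used the TMM-scaled library sizes, and levels are given as mean ± SD with n = 3 per group. Total counts of 34436497 to 36203230 per library set the counting precision. Intervals from counts cover counting error only, since reads without molecular identifiers are not independent molecules.

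Gene lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 between the genes of a list, for lists with at least 5 tested members. Camera asks whether a list's genes lie higher or lower than the other genes. Of 55 lists, 54 had enough tested members; the mitochondrially encoded genes did not. A list was called at an adjusted p under 0.05 over the 54 lists of a comparison. The same lists were tested with a correlation estimated from the residuals, and with fry, which asks whether a list's genes move one way on balance without setting them against other genes. In SBM against FM the estimate was 0.883 for the ovary and oocyte list, 0.728 for cytosolic ribosomal proteins and 0.631 for proliferation. It was 0.262 for interferon-stimulated genes and −0.011 for tight and adherens junctions. Where the estimate is far above 0.01, the p-values with the preset correlation treat genes that move together as nearly independent. They then do not measure the spread between samples. List members were also tested with the p adjusted over the list alone. That adjustment does not cover the other lists or comparisons. Members that move together tend to pass together, so the number passing is not a number of separate results. Of 1722 listed symbols, 1494 were found by symbol and 76 by synonym, 6 were ambiguous and 146 had no match. A list's level in a library is the mean over its members of log2 CPM (prior count 2), centred on the 9 libraries. Lists are not independent: of 1649 tested genes in any list, 127 stand in more than 1, and 68 pairs of lists share a tested gene. The absorptive enterocyte list of 38 tested genes shares 8 with lipid absorption (mogat2 and mtp among them), 5 with peptide and amino acid handling and 5 with carbohydrate digestion. Enteroendocrine cell and endocrine pancreas lists share 13, and goblet cell and mucin lists 9. The genes mmp9 and mmp13a stand in both the neutrophil and the inflammatory effector list. The ovary and testis lists share ddx4 and dazl, the ovary and proliferation lists ccnb1, and the interferon-stimulated and proteasome lists psmb8a, psmb9a, psmb10 and psmb12. The pattern used for ribosomal proteins also took in the kinase genes of the rps6k family.

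The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names the genes with the largest changes among those past the threshold, and, where fewer than 3 pass in a direction, the 3 with the smallest unadjusted p in that direction, given as not passing. It also names 14 genes of inflammation and the epithelial barrier, whether or not they pass; il6 was removed by the filter. Since no gene passed, the members named for a list below were chosen after their values were seen, as the 3 with the smallest unadjusted p in the list's direction, and some of these are left out. Members given as past the threshold over the list alone were likewise picked by their values. Alternatives were other scalings (RLE factors, library size only, library sizes without exocrine pancreas genes), DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), other filters and thresholds, a fit of the 6 libraries compared, the replicate number as a block, and leaving out each library in turn. After the data were seen, fits without the libraries highest in oocyte or hepatocyte genes, with the levels of those lists as covariates, with sample quality weights and with robust dispersions were added. The gene tests were checked on simulated data drawn from the real means, library sizes and spread, with a set of genes changed by known folds. Each comparison had 1 such set, drawn with edgeR's own dispersion per gene, equal in all groups and independent between genes. These sets lack the libraries that stand apart in the real data, and their spread is the one edgeR assumes.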

Results

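Transcript abundance was measured in 9 intestine libraries of zebrafish, a fish used as a model of diet-induced gut inflammation. The study title names an enteritis caused by soybean meal and a compound tested against it, β,β-dimethylacryloyl shikonin, an ester of the plant pigment shikonin. The libraries fall into 3 groups of 3, coded FM, SBM and D3. Total counts were 34436497, 36058318 and 35980562 in FM, 35484189, 36203230 and 34721741 in SBM, and 35386559, 35642442 and 36078662 in D3, and between 22961 and 24472 genes were detected per library. The 3 comparisons ask how SBM differed from FM, how D3 differed from SBM, and how D3 differed from FM. A last paragraph asks how much of the difference between SBM and FM was absent in D3. Levels are given as mean ± SD of CPM with n = 3 per group, and changes as log2 fold change ± SE.

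Several libraries carried transcripts of organs next to the intestine, and their levels differed widely between libraries of the same group. Zona pellucida genes, which encode the egg coat, were high in SBM library 1 and D3 library 3: zp3 was at 570 and 448 CPM there, at 69.4 in SBM library 3, and between 7.54 and 50.5 elsewhere. The ovary and oocyte list took 1.243% and 1.291% of the counts in those 2 libraries, 0.19% in SBM library 3, and 0.019 to 0.083% in the others. The listed epithelial gene epcam moved with the oocyte genes, at 636 and 669 CPM in the same 2 libraries, 121 in SBM library 3 and 21.6 to 43.7 elsewhere. Liver transcripts were high in 3 other libraries. The liver fatty acid binding protein gene fabp10a was at 3920 CPM in SBM library 2, 1760 in D3 library 1 and 2050 in D3 library 2, against 32.1 to 297 in the other 6. The egg yolk precursor gene vtg1, made in the female liver, reached 27000 CPM in D3 library 2 and 2250 in SBM library 2, against 8.32 to 49.5 in the rest. Exocrine pancreas genes were abundant in every library, from 9.56% of the counts in D3 library 2 to 21.81% in FM library 1. Across all tested genes, SBM library 1 correlated more closely with D3 library 3 (Spearman 0.975) than with either other SBM library, where the values within SBM were 0.869 to 0.92. The FM libraries correlated with each other at 0.973 to 0.976. These correlations are across genes, which are not independent replicates. They do not settle whether a sample was exchanged between SBM and D3, a doubt that bears on every mean of these 2 groups.

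**Figure D1:**
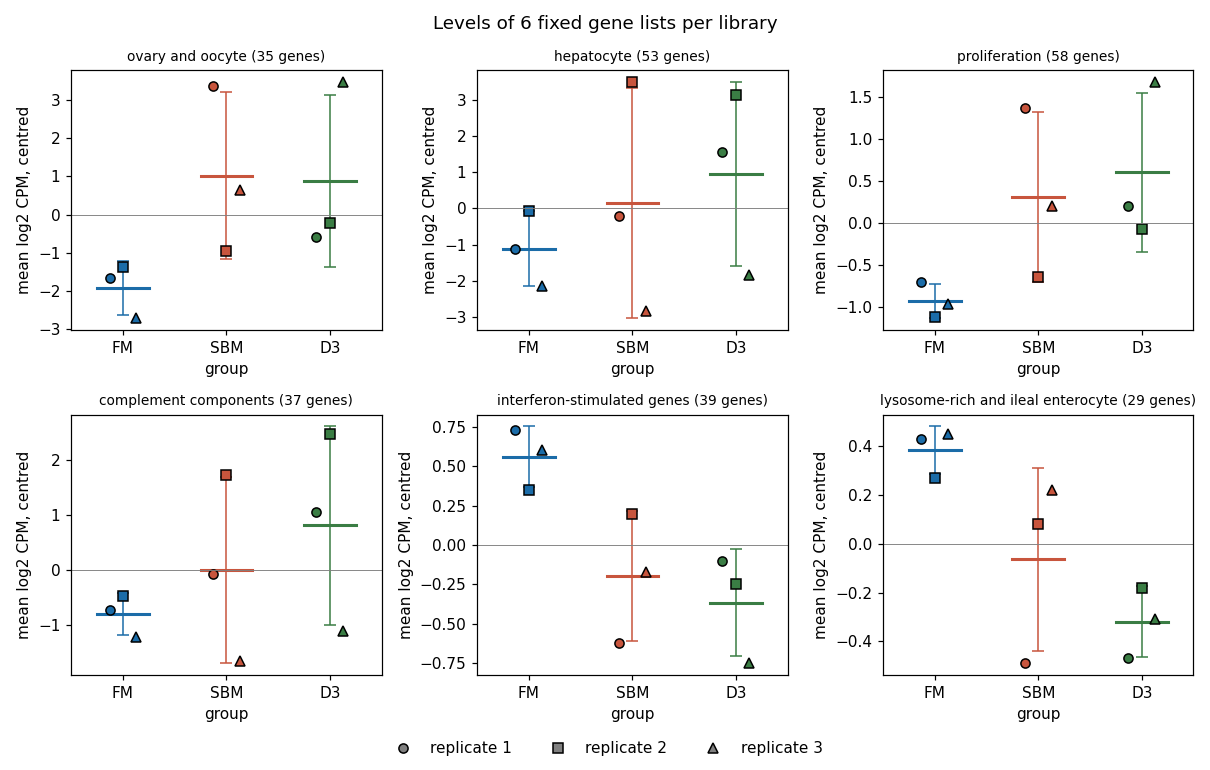
Levels of 6 gene lists in the 9 libraries, as mean log2 CPM over the list's genes, centred on all libraries (y axis), by group (x axis). Points are libraries, with a marker per replicate number, and bars give the mean ± SD of 3 libraries. Oocyte genes lie at 3.36 in SBM replicate 1 and 3.48 in D3 replicate 3, hepatocyte genes at 3.52 in SBM replicate 2 and 3.16 in D3 replicate 2, and interferon-stimulated genes lie higher in each FM library than in any other.

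In SBM against FM, the haem oxygenase gene hmox1a, which responds to oxidative stress, was at 165 ± 59.5 CPM in FM and 22.8 ± 9.34 in SBM, a log2 fold change of −2.85 ± 0.44. The gene ydjc stood at 26.9 ± 4.2 CPM in FM and 9.68 ± 0.861 in SBM (−1.48 ± 0.22), and the uncharacterised LOC110440163 at 33 ± 10.7 and 10.8 ± 1.67 (−1.60 ± 0.27). Among genes with higher values in SBM, the cytochrome P450 gene cyp2x7 was at 1.74 ± 0.532 CPM in FM and 18.1 ± 13.9 in SBM (3.37 ± 0.66). The unconventional myosin gene myo1hb was at 0.253 ± 0.0424 and 2.19 ± 1.24 (3.09 ± 0.50), and lrrc9 at 0.0648 ± 0.0581 and 0.655 ± 0.253 (3.28 ± 0.67). For each of these 6 genes the SBM and FM libraries did not overlap, but none passed the test, with an edgeR adjusted p of 0.54 for each. The test called 0 of 19450 genes, with a smallest adjusted p of 0.541, and 1738 genes had an unadjusted p under 0.05 (1075 higher, 663 lower), where 972 are expected by chance. Limma-voom called 0 genes and DESeq2 called 263, of which 228 were higher and 27 belong to the ovary and oocyte list. Without the 2 libraries highest in oocyte genes, and without the 3 highest in hepatocyte genes, edgeR again called 0. The 2 groups did not overlap for 3861 genes (19.9%), where chance gives 10%. The 972 and the 10% are averages. Genes that move together across libraries can put such counts far above or below them without a group effect. These counts are therefore no test, here and in the other 2 comparisons. In simulated data with the same spread, edgeR recovered 0% of 2-fold, 18.2% of 4-fold and 60.6% of 8-fold changes, with 1 false call, and DESeq2 recovered 4.5%, 52.2% and 87.9% with 58 false calls.

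Interferon-stimulated genes, the antiviral and immune signalling set, were lower in SBM than in FM, with a median log2 fold change of −0.61, 33 of 39 members negative and an adjusted p of 2.17e-09 (adjusted p = 0.597 with an estimated correlation). Their transcription factor gene stat1b was at 160 ± 47.2 CPM in FM and 72.4 ± 24.8 in SBM (−1.14 ± 0.36), and cmpk2 at 22.9 ± 6.49 and 7.66 ± 6.53 (−1.58 ± 0.54). Absorptive enterocyte genes were also lower (median −0.64, adjusted p = 1.92e-08, and adjusted p = 0.597 with an estimated correlation). Among them, the carotenoid-cleaving enzyme gene bco1 was at 322 ± 107 CPM in FM and 132 ± 66 in SBM (−1.29 ± 0.39), and the fat-resynthesis gene mogat2 at 139 ± 23.6 and 67.8 ± 26.5 (−1.03 ± 0.33). Fatty acid oxidation genes had a median of −0.34 with 40 of 41 members negative (adjusted p = 3.19e-06, and adjusted p = 0.629 with an estimated correlation). The carnitine palmitoyltransferase gene cpt1ab of that list was at 228 ± 26.1 and 121 ± 14.9 CPM (−0.91 ± 0.21). Lysosome-rich and ileal enterocyte genes, which mark the protein- and bile-acid-absorbing segment, had a median of −0.40 (adjusted p = 3.19e-06, and adjusted p = 0.597 with an estimated correlation). In that list the bile acid transporter genes slc51a and slc10a2 had log2 fold changes of −1.10 ± 0.29 and −0.82 ± 0.28. Peptide and amino acid handling genes (median −0.58, adjusted p = 6.31e-07) and xenobiotic metabolism genes (−0.45, adjusted p = 1.93e-06) were lower as well (adjusted p = 0.597 and 0.629 with an estimated correlation). In the xenobiotic list, cyp2k18 (123 ± 18.8 and 49.5 ± 8.44 CPM) and cyp2x7 passed with the p adjusted over the list alone, 1 lower and 1 higher, while 0 passed over all genes. The level in SBM library 2 was above FM for xenobiotic metabolism (0.54 against 0.14 to 0.4). It was within the FM range for absorptive enterocyte (0.43 against 0.19 to 0.52) and fatty acid oxidation genes (0.3 against 0.16 to 0.34). The same held for peptide and amino acid handling (0.33 against 0.19 to 0.38). Each SBM library lay below FM for interferon-stimulated and for lysosome-rich and ileal enterocyte genes.

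Immediate early genes, which include fosl2 (−0.96 ± 0.31) and dusp5 (−0.88 ± 0.26), were lower too, with a median of −0.53 (adjusted p = 6.31e-07, and adjusted p = 0.597 with an estimated correlation). Oxidative phosphorylation subunits had 83 of 85 members negative (median −0.27, adjusted p = 1.63e-07), and cytosolic ribosomal proteins 85 of 92 (median −0.35, adjusted p = 6.11e-08). For these the adjusted p was 0.629 and 0.638 with an estimated correlation. Exocrine pancreas genes lay at a median of −0.46 (adjusted p = 5.08e-06, and adjusted p = 0.629 with an estimated correlation). Lipid absorption and lipoproteins were called lower with a median of −0.48, although the mean was 0.06 (adjusted p = 7.61e-06, and adjusted p = 0.629 with an estimated correlation). The list of Nrf2 targets and antioxidant enzymes had a median of −0.23, which library size scaling alone turned positive, and an adjusted p of 0.00477 (adjusted p = 0.629 with an estimated correlation). Only hmox1a passed in it with the p adjusted over the list alone. The level in SBM library 2 was above every FM library for cytosolic ribosomal proteins (0.3 against 0.11 to 0.27). It was also above FM for lipid absorption genes (0.85 against −0.15 to 0.39) and the Nrf2 list (0.3 against −0.04 to 0.16). It was within the FM range for oxidative phosphorylation (0.07 against 0.06 to 0.18) and exocrine pancreas genes (0.54 against 0.13 to 0.57). For immediate early genes each SBM library lay below FM. Altogether 27 lists were lower and 5 higher of 54 tested. Without the 2 libraries highest in oocyte genes 18 were lower and 6 higher, and without the 3 highest in hepatocyte genes 29 and 3. Of the 27 lower lists, 17 were called lower in all of 10 settings that kept the preset correlation. Those settings were library size alone, the replicate block, and the 6 libraries left out in turn. The fits without the libraries highest in oocyte or hepatocyte genes were also among them. These 17 include all those named here except the Nrf2 list, which lost its call without the 2 libraries highest in oocyte genes (adjusted p = 0.065). Library size scaling turned the median positive in 8 of the 27, among them the circadian clock and the macrophage and dendritic cell lists of those 17. With an estimated correlation 0 of the 32 lists were called, and fry called 0. With library size alone the median difference of all genes was 0.231 in SBM against FM, 0.022 in D3 against SBM and 0.267 in D3 against FM, against −0.019, 0.014 and 0.007 with TMM factors.

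The lists higher in SBM than in FM were those of other organs, of dividing cells and of complement components. Proliferation genes had a median of 1.56, with 54 of 58 members positive (adjusted p = 2.59e-17, and adjusted p = 0.597 with an estimated correlation). The mitotic regulator gene foxm1 was at 2.33 ± 0.895 CPM in FM and 10.4 ± 6.18 in SBM (2.16 ± 0.55), and mki67 at 18.2 ± 5.69 and 42.2 ± 19.4 (1.21 ± 0.39). The ovary and oocyte list had a median of 4.08 with 33 of 35 members past the threshold when adjusted over the list alone and 0 over all genes (adjusted p = 2.59e-17, and adjusted p = 0.597 with an estimated correlation). Testis genes, which share germ cell genes such as ddx4 with it, had a median of 3.58 (adjusted p = 1.19e-08, and adjusted p = 0.597 with an estimated correlation). The testis level was highest within SBM in library 2 (1.52), where oocyte genes were low (−0.94), and there the meiosis gene sycp1 was at 13.4 CPM against 0.436 and 1.75 in the other SBM libraries. Proliferation moved with the oocyte list: its level was 1.37 in SBM library 1, −0.64 in SBM library 2 and 0.21 in SBM library 3, against −1.11 to −0.70 in FM. Its median was 0.77 without the 2 libraries highest in oocyte genes. Hepatocyte genes were higher with a median of 3.15 (adjusted p = 7.61e-06, and adjusted p = 0.663 with an estimated correlation), which rested on SBM library 2: without it the median was −0.21 (adjusted p = 0.09). Complement components followed, with a median of 1.24 (adjusted p = 0.0439, and adjusted p = 0.764 with an estimated correlation). The complement components call ended without FM library 2 (adjusted p = 0.071), FM library 3 (0.12) or SBM library 2 (0.43), and with library size scaling (0.093).

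Of the 14 genes of inflammation and barrier fixed in advance, il6 was too low to be tested, and none of the others passed with edgeR in any comparison, while DESeq2 called 1 of them, hmox1a, lower in SBM and in D3 than in FM. The interleukin gene il1b was at 5.74 ± 0.391 CPM in FM, 7.25 ± 1.56 in SBM and 13.7 ± 12.1 in D3. The tumour necrosis factor gene tnfa was at 2.59 ± 1.25, 1.51 ± 0.976 and 0.838 ± 0.391 CPM, and the neutrophil chemokine gene cxcl8a at 9.96 ± 2.01, 5.11 ± 1.48 and 4.8 ± 2.67. The matrix protease gene mmp9 was at 3.42 ± 1.46, 3.44 ± 1.22 and 7.34 ± 1.62 CPM, and each D3 library lay above every SBM and FM library. In D3 against SBM mmp9 had a log2 fold change of 1.09 ± 0.43, with an edgeR unadjusted p of 0.032 and an adjusted p of 1. In D3 against FM tnfa had −1.63 ± 0.61 (unadjusted p = 0.027, adjusted p = 0.32), and each D3 library lay below every FM library. Each library also lay below every FM library for cxcl8a and hmox1a in SBM and in D3, and for ptgs2a and tjp1a in SBM. The log2 fold change of cxcl8a was −0.96 ± 0.48 in SBM and −1.05 ± 0.48 in D3 (unadjusted p = 0.078 and 0.058), and that of tjp1a, −0.16 ± 0.15 in SBM, turned to 0.12 with library size scaling. The tight junction gene tjp1a stood at 64.4 ± 1.55, 57.6 ± 1.66 and 57.8 ± 5.54 CPM, and oclna at 85.2 ± 13.2, 74 ± 19.4 and 79.1 ± 30.1. The anti-inflammatory il10 was at 0.453 ± 0.491, 0.698 ± 0.544 and 0.551 ± 0.327 CPM, and tgfb1a at 2.2 ± 0.124, 2.13 ± 0.509 and 1.88 ± 0.344. The prostaglandin synthase gene ptgs2a was at 1.37 ± 0.488, 0.544 ± 0.247 and 1.11 ± 0.735 CPM, and nos2a at 1.08 ± 0.555, 1.39 ± 0.224 and 0.936 ± 0.293. The signalling genes myd88 (18.3 ± 4.52, 19.6 ± 4.33 and 16.5 ± 1.75 CPM) and rela (14.2 ± 1.63, 12.3 ± 3.1 and 13.1 ± 3.59) differed by less than their spread. In SBM against FM the list of inflammatory effectors was not called (median −0.15, adjusted p = 0.322), nor were Toll-like receptor and NF-kB signalling (−0.12, adjusted p = 0.111), neutrophil genes (0.02, adjusted p = 0.868) and tight and adherens junctions (−0.15, adjusted p = 0.158). Pro-inflammatory cytokines and chemokines were lower in SBM, with a median of −0.44 (adjusted p = 0.00136, and adjusted p = 0.629 with an estimated correlation). The list's level was −0.27, −0.14 and 0.09 in SBM against 0.42, 0.02 and 0.37 in FM, so the libraries overlapped. In that list il22 was at 5.49 ± 1.7 CPM in FM and 1.92 ± 0.831 in SBM. Of the 4 lists of immune cell markers 2 were called lower beside it, and neutrophil genes and the B lymphocyte and plasma cell list (adjusted p = 0.33) were not called. T and NK lymphocyte genes had a median of −0.42 (adjusted p = 0.00018, and adjusted p = 0.597 with an estimated correlation). Macrophage and dendritic cell genes had a median of −0.27, which library size scaling turned to 0.02 (adjusted p = 0.00678, and adjusted p = 0.629 with an estimated correlation). The level of both lists was lower in each SBM library than in any FM library.

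**Figure D2:**
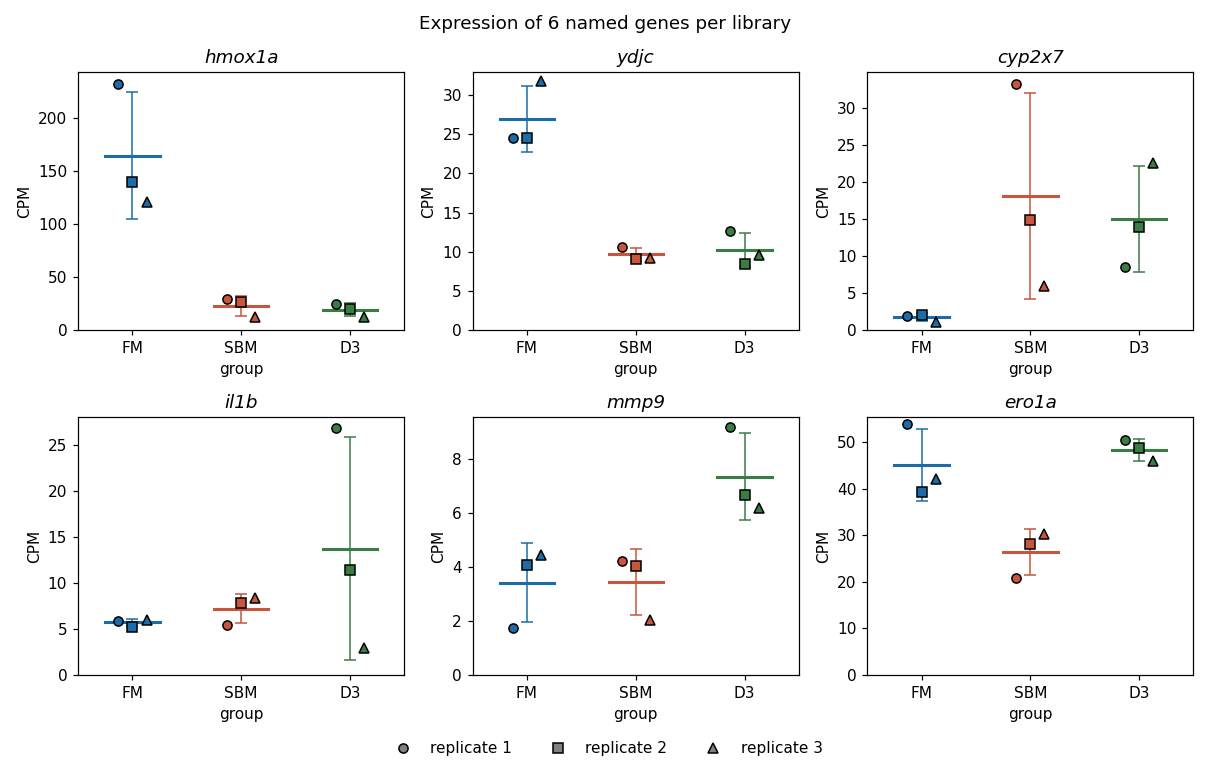
Expression of hmox1a, ydjc, cyp2x7, il1b, mmp9 and ero1a in CPM (y axis, linear from 0) by group (x axis). Points are libraries, with a marker per replicate number, and bars give the mean ± SD of 3 libraries. The FM libraries lie apart from the other 6 in the first 3 panels, and the D3 libraries lie above the SBM libraries for mmp9 and ero1a.

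In D3 against SBM, ero1a, which encodes an oxidase of the endoplasmic reticulum, was at 26.3 ± 4.96 CPM in SBM and 48.3 ± 2.31 in D3 (0.87 ± 0.20), beside 45 ± 7.67 in FM. The complement gene c7b was at 2.03 ± 1.17 CPM in SBM and 79.3 ± 106 in D3, with 4.82, 201 and 31.9 CPM in the 3 D3 libraries. Its log2 fold change was 5.28 ± 1.22, and 3.17 without D3 library 2. The uncharacterised LOC100329579 was at 315 ± 49.7 CPM in SBM, 45.9 ± 8.91 in D3 and 356 ± 194 in FM (−2.78 ± 0.45). The retinal matrix gene impg2b was at 0.495 ± 0.0239 and 0.0938 ± 0.0453 CPM (−2.34 ± 0.44), and LOC110440138 at 0.624 ± 0.143 and 1.68 ± 0.251 (1.43 ± 0.33). The uncharacterised si:dkey-18p12.4 was nearly absent from D3, with 4 counts over 3 libraries against 5896 in SBM and 2403 in FM. That is a ratio of 1480 for SBM over D3 (exact 95% interval 579 to 5450). The SBM libraries held 325, 1171 and 4400 of those counts, and the ratio was 559 without SBM library 3 and 984 without D3 library 3. None of these passed: the edgeR adjusted p was 0.78 for si:dkey-18p12.4 and 1 for the others. The test called 0 genes (smallest adjusted p 0.781), limma-voom called 0, and 402 had an unadjusted p under 0.05, below the 972 expected. DESeq2 called 6, and the genes named next were chosen after their values were seen. It put c7b and the transcobalamin-like tcnl higher, and LOC100329579, si:dkey-18p12.4, rnasel2 and si:dkeyp-98a7.4 lower. The groups did not overlap for 886 genes (4.6%), where chance gives 10%. Without the 2 libraries highest in oocyte genes, and without the 3 highest in hepatocyte genes, edgeR called 0. In simulated data of this comparison edgeR recovered 12.3% of 4-fold and 56.9% of 8-fold changes.

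Oxidative phosphorylation subunits were higher in D3 than in SBM, with 80 of 85 members positive, a median of 0.25 and an adjusted p of 5.24e-10 (adjusted p = 0.954 with an estimated correlation). Among them ndufa4 was at 264 ± 54.8 CPM in FM, 136 ± 31.8 in SBM and 230 ± 46.1 in D3 (0.76 ± 0.27), and atp5ia at 31.4 ± 1.53, 24.1 ± 5.35 and 36 ± 1.03 (0.58 ± 0.19). Proteasome subunits, which degrade tagged proteins, were higher as well, with a median of 0.34 and 38 of 43 members positive (adjusted p = 1.46e-06, and adjusted p = 0.954 with an estimated correlation). At an edgeR unadjusted p under 0.05, 2 members were higher and 3 lower. The members psmb8a, psmb9a and psmb10 lay lower in each D3 library than in any SBM library. The D3 and SBM libraries overlapped in both lists. The level of oxidative phosphorylation subunits was 0.28, 0.12 and −0.23 in D3 against −0.41, 0.07 and −0.21 in SBM. That of proteasome subunits was 0.36, 0.12 and −0.02 in D3 against 0, −0.24 and 0.13 in SBM. These calls of oxidative phosphorylation subunits and proteasome subunits held without each single library and without the 2 libraries highest in oocyte genes. They ended without the 3 libraries highest in hepatocyte genes, where D3 has 1 library left (medians −0.01 and −0.13, adjusted p = 0.9 and 0.29). Enteric neuron and glia genes were lower, with a median of −0.19 (adjusted p = 0.00136, and adjusted p = 0.912 with an estimated correlation). In that list hand2 was at 6.01 ± 1.24 CPM in SBM and 3.98 ± 0.261 in D3. The list's level was −0.3, −0.4 and 0.03 in the D3 libraries against 0.07, 0.13 and −0.06 in SBM, so these overlapped too. The call of enteric neuron and glia held without each single library and ended without the 3 libraries highest in hepatocyte genes (adjusted p = 0.53).

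The other lists called in D3 against SBM depended on single libraries. Complement components were higher (median 0.50, adjusted p = 3.08e-05, and adjusted p = 0.954 with an estimated correlation), but the call ended without SBM library 1 (adjusted p = 0.11), SBM library 3 (0.14) or D3 library 2 (median −0.36, adjusted p = 0.6). Their level followed the hepatocyte genes, at 1.73 in SBM library 2, 1.06 in D3 library 1 and 2.48 in D3 library 2 against −1.67 to −0.07 in the other 6. Inflammatory effectors, which include mmp9, were higher (median 0.35, adjusted p = 0.00795, and adjusted p = 0.954 with an estimated correlation). That call of inflammatory effectors ended without SBM library 1 (adjusted p = 0.16), D3 library 1 (0.8) or D3 library 2 (0.24). Without the 3 libraries highest in hepatocyte genes, inflammatory effectors were lower (median −0.72, adjusted p = 0.003). The neutrophil list, which also holds mmp9, was higher too (median 0.24, adjusted p = 0.000935, and adjusted p = 0.954 with an estimated correlation). That call of neutrophil genes ended without SBM library 1 (adjusted p = 0.11), D3 library 1 (0.21) or D3 library 2 (0.11), and without the 3 libraries highest in hepatocyte genes (median −0.27, adjusted p = 0.21). Proliferation genes were higher (median 0.22, adjusted p = 0.000935, and adjusted p = 0.954 with an estimated correlation). Their median was −0.12 without SBM library 2 (adjusted p = 0.27) and −0.55 without D3 library 3 (adjusted p = 0.15), so the direction of proliferation turned. Lysosome-rich and ileal enterocyte genes were lower (median −0.39, adjusted p = 0.000104, and adjusted p = 0.954 with an estimated correlation), with fabp6 at 5560 ± 2210 CPM in SBM and 3300 ± 600 in D3. That call of lysosome-rich and ileal enterocyte genes ended without SBM library 3 (adjusted p = 0.27) or D3 library 3 (0.056). Interferon-stimulated genes were lower (median −0.14, adjusted p = 0.0442, and adjusted p = 0.954 with an estimated correlation), a call that ended without SBM library 2 (adjusted p = 0.67), SBM library 3 (0.23) or D3 library 3 (0.41), with a median of 0.18 and 0.05 in the first and last of these.

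Exocrine pancreas genes were lower in D3 than in SBM (median −0.32, adjusted p = 3.08e-05, and adjusted p = 0.954 with an estimated correlation), which ended without SBM library 2 (adjusted p = 0.89) or D3 library 2 (0.15). Testis genes were lower (median −0.36, adjusted p = 0.00164, and adjusted p = 0.954 with an estimated correlation). The testis call ended without SBM library 2 (adjusted p = 0.4), D3 library 1 (0.21) or D3 library 2 (0.24). Hepatocyte genes were called higher with a mean of 0.32 but a median of −0.11, which library size scaling turned to 0.13 (adjusted p = 0.03, and adjusted p = 0.954 with an estimated correlation). The hepatocyte median was 3.13 without SBM library 2 and −0.70 without D3 library 2. The ovary and oocyte list was not called (median −0.02, adjusted p = 0.731), and neither were cytosolic ribosomal proteins (0.05, adjusted p = 0.329). Of 54 lists, 12 were higher and 9 lower. The split was 18 and 3 without SBM library 2, 19 and 4 without D3 library 3, 5 and 16 without SBM library 1, 6 and 12 without D3 library 1, and 4 and 11 without D3 library 2. It was 13 and 8 without the 2 libraries highest in oocyte genes, and 3 and 17 without the 3 highest in hepatocyte genes. No list was called in the same direction in all 10 settings with the preset correlation, and 0 were called with an estimated correlation or by fry.

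In D3 against FM, hmox1a was at 165 ± 59.5 CPM in FM and 19.1 ± 6.14 in D3 (−3.11 ± 0.44). The gene impg2b was at 0.867 ± 0.0952 and 0.0938 ± 0.0453 CPM (−3.15 ± 0.45), and si:dkey-18p12.4 had 604 times the counts in FM (exact 95% interval 236 to 2220), or 401 times without D3 library 3. Higher values in D3 were seen for the translation regulator gene cpeb4a, at 6.33 ± 1.06 and 30.9 ± 10.3 CPM (2.29 ± 0.44). The gene hpdl was at 0.521 ± 0.156 and 2.69 ± 0.863 CPM (2.36 ± 0.45), and myo1hb at 0.253 ± 0.0424 and 1.65 ± 0.171 (2.69 ± 0.49). The 2 groups did not overlap for these genes, and none passed, with an edgeR adjusted p of 0.32 for each. The test called 0 genes (smallest adjusted p 0.32), limma-voom called 0, and 2954 genes had an unadjusted p under 0.05 (1565 higher, 1389 lower) where 972 are expected. DESeq2 called 895, of which 621 were higher, 274 lower and 29 in the ovary and oocyte list. The groups did not overlap for 5127 genes (26.4%), where chance gives 10%. Because genes move together, neither this count nor the 2954 is a test of a group difference. Without the 2 libraries highest in oocyte genes edgeR called 0. Without the 3 highest in hepatocyte genes it called 2053, of which 1837 were higher, with D3 represented only by the oocyte-rich library 3. In simulated data of this comparison edgeR recovered 10.6% of 4-fold and 60% of 8-fold changes with 1 false call, and DESeq2 53.7% and 83.3% with 60.

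Lysosome-rich and ileal enterocyte genes were lower in D3 than in FM, with a median of −0.87 and an adjusted p of 1.38e-10 (adjusted p = 0.452 with an estimated correlation). Of 29 members, 14 passed when adjusted over the list alone against 0 over all genes. The estimated correlation between members was 0.354, so these 14 are not separate results. The bile acid transporter gene slc10a2 was at 885 ± 166 CPM in FM and 389 ± 88.4 in D3 (−1.19 ± 0.28), slc51a at 114 ± 29.6 and 46.9 ± 8.15 (−1.28 ± 0.29), and tmigd1 at 538 ± 67.8 and 224 ± 44.8 (−1.27 ± 0.26). Peptide and amino acid handling genes were lower (median −0.64, adjusted p = 8.23e-08, and adjusted p = 0.46 with an estimated correlation), with 15 members lower and 1 higher when adjusted over the list alone. Among them the peptide transporter gene slc15a2 was at 1020 ± 130 CPM in FM and 435 ± 99 in D3 (−1.23 ± 0.23). Smooth muscle genes were lower (median −0.70, adjusted p = 1.45e-09, and adjusted p = 0.452 with an estimated correlation), with 11 past the threshold over the list alone. The contractile gene cnn1b in it was at 76.6 ± 1.25 and 38.7 ± 5.7 CPM (−0.98 ± 0.20). Interferon-stimulated genes had a median of −0.98 (adjusted p = 1.38e-10, and adjusted p = 0.452 with an estimated correlation), with cmpk2 at 22.9 ± 6.49 and 5.43 ± 0.791 CPM (−2.07 ± 0.55). Enteroendocrine cell genes (median −0.65, adjusted p = 6.6e-07) and immediate early genes (−0.59, adjusted p = 2.1e-07) were lower, with 5 and 1 members past the threshold over the list alone (adjusted p = 0.452 for both with an estimated correlation). The 1 immediate early gene was nr4a1, at 19.9 ± 11.9 and 4.5 ± 0.229 CPM, and the 5 enteroendocrine genes were insl5b, adcyap1a, scg2b, tac3a and fev. In the xenobiotic metabolism list (median −0.44, adjusted p = 1.5e-05, and adjusted p = 0.669 with an estimated correlation) cyp2k18, abcg2b and abcb4 were lower and cyp2x7 higher over the list alone.

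The clock genes per1b, per2, per3, nr1d1, dbpa, tefa, bhlhe41 and rorab made up the 8 members of the circadian clock list that were lower in D3 than in FM when adjusted over the list alone, with per1b at 51.4 ± 4.54 CPM in FM and 28.4 ± 2.93 in D3 (−0.86 ± 0.19). The list's median was −0.04, which library size scaling turned positive (adjusted p = 0.0165, and adjusted p = 0.716 with an estimated correlation). The circadian clock call ended without FM library 2 (adjusted p = 0.062) or D3 library 2 (0.12). Exocrine pancreas genes had a median of −0.79 (adjusted p = 8.71e-11, and adjusted p = 0.622 with an estimated correlation). Proliferation genes were higher in D3 (median 1.86, adjusted p = 7.32e-20, and adjusted p = 0.46 with an estimated correlation), with 32 of 58 past the threshold over the list alone, and mki67 was at 59.7 ± 10.1 CPM against 18.2 ± 5.69 in FM (1.71 ± 0.39). They were higher beside the ovary and oocyte list (median 4.06, adjusted p = 4.6e-12, and adjusted p = 0.669 with an estimated correlation) and the testis list (2.12, adjusted p = 0.00111, and adjusted p = 0.669 with an estimated correlation). Hepatocyte genes (median 3.04, adjusted p = 2.1e-07) and complement components (2.49, adjusted p = 7.11e-05) were higher together (adjusted p = 0.716 for both with an estimated correlation). Both were lower without the 3 libraries highest in hepatocyte genes, at medians of −1.07 (hepatocyte) and −0.62 (complement components). Those libraries were chosen by the hepatocyte list itself, and the fit leaves D3 with library 3 alone, so this turn is no independent test. The complement call ended without D3 library 2 (adjusted p = 0.13). Proteasome subunits were higher (median 0.40, adjusted p = 0.000298, and adjusted p = 0.7 with an estimated correlation), a call of proteasome subunits that ended without D3 library 1 (adjusted p = 0.075). Cytosolic ribosomal proteins were lower (median −0.30, adjusted p = 6.16e-05, and adjusted p = 0.727 with an estimated correlation), which ended without D3 library 3 (adjusted p = 0.087). Of 54 lists 7 were higher and 24 lower, with 12 and 13 without D3 library 3, 11 and 13 without the 2 libraries highest in oocyte genes, and 3 and 36 without the 3 highest in hepatocyte genes. In all 10 settings with the preset correlation, 3 of the 7 higher lists (proliferation, ovary and oocyte, testis) and 10 of the 24 lower ones were called. With an estimated correlation or by fry 0 were.

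The last comparison sets the difference between SBM and FM beside that between D3 and SBM. The level of hmox1a did not return, at 22.8 ± 9.34 CPM in SBM and 19.1 ± 6.14 in D3, and neither did ydjc, at 9.68 ± 0.861 and 10.2 ± 2.13, against 165 ± 59.5 and 26.9 ± 4.2 in FM. Oxidative phosphorylation subunits were lower in SBM than in FM and higher in D3 than in SBM, and in D3 against FM their median was −0.02 (adjusted p = 0.45). The lists of absorptive enterocyte, fatty acid oxidation, lipid absorption and lipoproteins, and Nrf2 targets and antioxidant enzymes were also called lower and then higher, and the testis list higher and then lower. In D3 against FM absorptive enterocyte (median −0.39, adjusted p = 0.000476) and fatty acid oxidation genes (−0.22, adjusted p = 0.00776) were still called lower (adjusted p = 0.716 and 0.727 with an estimated correlation), calls that ended without D3 library 3 (0.072 and 0.54), and library size scaling turned the fatty acid oxidation median there to 0.03. In D3 against SBM each of the first 4 calls ended without SBM library 1, SBM library 3, D3 library 1 or D3 library 2 (adjusted p from 0.1 to 0.91). Opposite directions are no evidence of a return on their own, because both comparisons contain the SBM libraries. Each of these D3 calls ended or turned without the 3 libraries highest in hepatocyte genes. That fit leaves D3 with the oocyte-rich library 3 alone, so it cannot decide on a return either. Interferon-stimulated, lysosome-rich enterocyte, exocrine pancreas, smooth muscle, enteroendocrine cell, and fibroblast and extracellular matrix lists were called lower in both steps, and proliferation, complement and hepatocyte lists higher in both. The D3 against SBM calls of smooth muscle, enteroendocrine cell and fibroblast genes ended without SBM library 2 or D3 library 3 (adjusted p from 0.067 to 0.65), and that of fibroblast genes also without D3 library 2 (0.11). In SBM against FM the enteroendocrine call ended without SBM library 1 (0.087). The fibroblast call there ended without FM library 3 (0.12), SBM library 1 (0.06) or SBM library 3 (0.18), and library size scaling turned its median to 0.06. With an estimated correlation none of these 15 lists was called, with an adjusted p of 0.954 for each in D3 against SBM and of 0.597 to 0.764 in SBM against FM. No gene was called in both comparisons with edgeR, in the same or the opposite direction. DESeq2 called 2 that were higher in SBM than in FM and lower in D3 than in SBM, rnasel2 and si:dkeyp-98a7.4. Of these rnasel2 was high in SBM libraries 1 and 2 (22 and 94.8 CPM) and not in library 3 (0.168), and si:dkeyp-98a7.4 was high in SBM library 1 (52.8 CPM) against 0.751 and 3.16 in the other two. Across the 19450 genes, the fold changes of the 2 comparisons correlated at −0.07, which single libraries moved: it was −0.32 without SBM library 2, −0.36 without SBM library 3, 0 without SBM library 1, 0.12 without D3 library 1, 0.03 without D3 library 2 and −0.57 without D3 library 3. The correlation is across genes, which are not independent replicates. Because both contain the SBM libraries, 20 simulations without any effect gave a mean of −0.5 (SD 0.012). They drew each gene independently, with the same dispersion in all groups, and held no oocyte or hepatocyte differences between libraries. Their SD is therefore narrower than the real libraries allow, and the distance from −0.5 cannot be read as an effect. The covariance was −0.04 against a simulated −0.21, a difference of 0.17. Signs were opposite for 49.5% of genes against 66.7% in the simulations. With 3 SBM libraries, the SBM libraries could not be split into parts of at least 2, so the part that comes from sharing them could not be set apart. The share of the SBM difference taken back in D3, planned over called genes, could not be computed because no gene was called. Over the 147 genes at an unadjusted p under 0.01, a limit set after the data were seen, it was 0.12. With the genes chosen without 1 SBM library, and D3 then set against that library, it was 0.1 over 48 genes for library 1, −0.46 over 412 for library 2 and −0.32 over 192 for library 3.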

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

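The fits without the libraries highest in oocyte or hepatocyte genes, with covariates, with sample quality weights and with robust dispersions, the share taken back, and the correlation of fold changes and the count ratio of si:dkey-18p12.4 without single libraries were chosen only after the data were seen. The count of genes called by edgeR stayed at 0 in all 3 comparisons under RLE factors, library size alone, library sizes without pancreas genes, other filters, the looser threshold of 0.1, robust dispersions, a fit of the 6 libraries compared, and each single library left out. Limma-voom and limma-trend also called 0.

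DESeq2 called 263 genes in SBM against FM (228 higher, 35 lower), 6 in D3 against SBM (2 higher, 4 lower) and 895 in D3 against FM (621 higher, 274 lower), and 2 genes that changed back. In simulated data it also made 58, 64 and 60 false calls where edgeR made 1 in each. Those data were drawn from edgeR's own dispersions, so the counts may favour edgeR. With oocyte and hepatocyte levels as covariates, 1 gene, si:dkey-18p12.4, was called lower in D3 against SBM. Without the 3 libraries highest in hepatocyte genes, D3 against FM gave 2053 (1837 higher, 216 lower), where D3 has 1 library that is assumed to vary like the other groups. Voom with sample quality weights gave 27 in D3 against FM, 25 lower and 2 higher (si:ch1073-67j19.1 and zgc:173443). The weights were 0.329 for SBM library 1 and 0.214 for D3 library 3, against 0.74 to 2.313 for the others. The cause of these differences was not tested.

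The 32, 21 and 31 called lists fell to 0, 0 and 0 with an estimated correlation, and to 0, 0 and 0 with fry. Library size scaling gave 31, 21 and 35 lists. The share of the SBM difference that D3 takes back was 0.12. It became −0.46 and −0.32 when the genes were chosen without SBM library 2 or 3 and D3 was set against that library. With SBM library 1 treated in this way the share kept its sign. The correlation of fold changes, −0.07, was −0.5 in simulated unchanged groups with genes drawn independently. It ran from −0.57 without D3 library 3 to 0.12 without D3 library 1. The cause was not tested.

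Of the single genes named, none passed in the edgeR fit. For 296 values, DESeq2, library size alone, the block, the fit of the 6 libraries compared and single libraries left out gave 2838 with the same sign and side of the threshold, 73 that now passed, each of them with DESeq2, and 46 that reversed. The covariate fit, not counted here, also called si:dkey-18p12.4. Library size scaling turned 4 in SBM against FM, to 0.19 for tgfb1a, 0.05 for rela, 0.12 for tjp1a and 0.07 for oclna. In D3 against FM it turned 6, to 0.03 for tgfb1a, 0.05 for nos2a, 0.12 for myd88, 0.13 for rela, 0.11 for tjp1a and 0.18 for oclna. Each of these lies below the median of all genes with that scaling, 0.231 and 0.267 (−0.019 and 0.007 with TMM factors). In D3 against SBM tjp1a was at −0.01 with library size scaling and with only the 6 libraries compared.

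Leaving out single libraries turned the sign of the following. In SBM against FM, il10 ran from −0.23 to 1.95, tgfb1a from −0.23 to 0.10, mmp9 from −0.32 to 0.26 and myd88 from −0.11 to 0.23. In D3 against SBM, il1b ran from −0.01 (without D3 library 1) to 1.39, cxcl8a from −0.38 to 0.30, il10 from −0.77 to 0.48, rela from −0.12 to 0.26, tjp1a from −0.08 to 0.04 and oclna from −0.26 to 0.32. There tekt1 ran from −2.91 to 1.62, and without D3 library 2 the yolk genes turned, with vtg3 from −5.65 to 8.1, vtg2 from −5.58 to 8.04 and vtg1 from −5.34 to 7.95. In D3 against FM, il10 ran from −0.25 to 1.61, nos2a from −0.55 to 0.19, ptgs2a from −0.87 to 0.10, rela from −0.34 to 0.05, oclna from −0.46 to 0.09, vtg3 from −0.71 to 9.28 and vtg1 from −1.02 to 8.48. The cause was not tested.

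By correlation, the replicate numbers did not pair the samples in every pair of groups. Deviations of same-numbered libraries correlated at 0.073, 0.183 and 0.288 between FM and SBM, at −0.578, 0.519 and −0.031 between SBM and D3, and at −0.069, 0.021 and −0.07 between FM and D3. Between FM and SBM, each FM library correlated best with its own number, while SBM library 1 correlated slightly better with FM library 2 (0.086). Elsewhere not every library did so: SBM library 1 and D3 library 3 reached 0.708. A pairing is therefore not shown, and it is not excluded. With the replicate number as a block, edgeR called 0 genes in each comparison, 0 changed back, and 31, 21 and 30 lists were called. The block turned mmp9 in SBM against FM to −0.03 and il10 in D3 against SBM to 0.19.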

Other observations

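The counts of genes over other splits of the samples, the test of dividing cells, the test of scaling for hmox1a and the test of whether FM stands apart were chosen only after the results were seen. Splitting the 6 libraries of a comparison into 3 and 3 in the 10 possible ways is too few for a share under 0.05. For genes, 10 of 10 splits gave as many calls as the real split in each comparison, which was certain because the real split called 0. The real counts were 0, and the highest of the others were 0 in SBM against FM, 3082 in D3 against SBM and 0 in D3 against FM. The split with 3082 genes set SBM library 1, SBM library 3 and D3 library 3 against SBM library 2, D3 library 1 and D3 library 2. It points to a structure of the samples, and it parts the libraries by hepatocyte genes and by oocyte genes: the first 3 have oocyte levels of 3.36, 0.64 and 3.48, and the other 3 −0.94, −0.58 and −0.23. For lists, 2 splits gave as many calls in SBM against FM (32 in the real split, 34 the highest other), 8 in D3 against SBM (21 and 32) and 4 in D3 against FM (31 and 35).

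Proliferation genes were called higher in SBM and D3 than in FM with the preset correlation. With an estimated one they were not (camera adjusted p = 0.597 and 0.46). Their level was highest in the 2 libraries rich in oocyte genes. If oocyte RNA were the whole cause, the excess in the other 4 libraries should follow their oocyte share. The observed excess over FM was 0.343 times the predicted one in SBM library 2, 1.82 in SBM library 3, 6.85 in D3 library 1 and 2.69 in D3 library 2, over 57 genes outside the oocyte list. The ratio was above 2 in both D3 libraries and below 2 in both SBM libraries, so the test does not decide. More dividing cells may contribute, since those 4 libraries lay 0.84 above FM on the log2 scale. An exact permutation over 35 splits did not tell this from chance (p = 0.057). The level of the whole list was −0.64 in the lowest of them and −0.70 in the highest FM library. In SBM library 2 the 57 genes summed to 854 CPM, against an FM mean of 834. Oocyte RNA would raise the same values, so both stay open.

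Complement components were called higher in D3 than in SBM with the preset correlation, but not with an estimated one (camera adjusted p = 0.954). The call also ended without D3 library 2. The level of the list followed the hepatocyte list over the 9 libraries, with a Pearson r of 0.98 (exact permutation p = 3e-05). The Spearman rho was 0.97 (exact permutation p = 0.00017). Without the 2 libraries farthest from the median, r was again 0.98, and no other pair of lists was tested in this way. The 2 lists share no gene. Liver RNA in some libraries is a candidate source of most of the difference: of 0.82 between D3 and SBM, 0.32 was left after the hepatocyte level, against a residual SD of 0.29. Expression in the intestine itself would leave a remainder above that SD, and 0.32 met this by a narrow margin. The SD is that of single libraries, not of a difference of group means. Among liver genes, fabp10a was at 3920 CPM in SBM library 2 and 2050 in D3 library 2. For vtg1 the values were 2250 and 27000, so 1 hepatocyte level does not describe all liver RNA. The remainder therefore does not tell intestine from liver, and 3 libraries against 3 cannot give an exact p below 0.1. Both explanations therefore stay open.

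The lower hmox1a in SBM and D3 is not what dilution by RNA of other organs would give. In each of the 6 libraries hmox1a lay further below FM than the lowest of the intestinal lists, with a gap of −1.54 on the log2 scale in SBM library 1, the smallest, and −2.90 in D3 library 3, the largest. The values argue against scaling between libraries as well: with library size alone, the fold change nearer 0 of the 2 comparisons with FM was −2.61. An effect of the treatments stays open and untested, and so does a difference of the FM samples for another reason: immediate early genes, which respond to handling, were 0.54 higher in FM than in the other 6 libraries, which cannot be told apart from the groups in this design.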
